A study of Drosophila melanogaster with 10 samples.

How the data were processed

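RNA was measured by sequencing in brains of male Drosophila melanogaster of the w1118 genotype, a white-eyed laboratory strain, aged 4 to 7 days. Per the labels, brains were dissected and flash frozen, RNA was taken with Trizol and libraries followed standard Illumina protocols. The 10 libraries were grouped by the diet in their titles: 5 from flies on a low-protein, high-carbohydrate diet (LPHC, protein to carbohydrate 0 to 1) and 5 from flies on a high-protein, low-carbohydrate diet (HPLC, 1 to 2), both at 360 g per L. The labels do not say whether the 5 libraries of a diet came from separate cultures or pools of flies, so the p-values measure the spread between these libraries, which may be partly technical.

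The authors deposited 1 table of normalised read counts per gene for all 10 libraries, a signal that is never negative. HISAT2, a read aligner, is named in the submitters' processing notes. The aligner version, the counting tool, its strand setting, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. In the deposited values, every gene in a library was a whole multiple of 1 constant. This held for 100% of values, within a tolerance of 1e-06 of a whole number. The constants were the reciprocals of the median-of-ratios size factors that DESeq2 computes. Those size factors had a ratio of 1.00 to factors recomputed from the recovered reads. Each deposited signal is therefore a whole read count divided by a library's size factor. The table lists 11621 genes, each with at least 1 read in 6 or more of the 10 libraries. A gene read in only 1 of the diets could not pass that condition and is not analysed here. Of the gene names, 11080 were current symbols in the reference gene table, 514 matched an older name and 27 matched none, 5 of which were bare numbers.

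The recovered reads summed to between 19834344 and 38402635 per library. A count of 3 reads corresponds to a normalised count of 2.09 in the deepest library and 4.19 in the shallowest, and values near these carry counting error of their own size. No pair of libraries of a diet agreed within sampling noise: chi-square per degree of freedom between pairs ran from 5.06 to 50.5.

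The main test was limma-trend (limma 3.58.1 in R 4.3.3, robust empirical Bayes) on log2 of the normalised count plus a pseudocount of 1, two-sided, over the 9896 genes with a mean of at least 10. The other 1725 genes were left out. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. All log2 fold changes are HPLC minus LPHC on the log2(value + 1) scale, which understates changes of low genes, and errors given with them are standard errors (SE). Means are given with the SD over 5 libraries. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

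Before the data were examined, 39 gene lists were fixed: pathways of nutrient use, stress and immunity, neural signalling, taste, and markers of cell types that a dissected brain could hold. The mitochondrial genome list had no member in the table, and names of other lists that were not found in it are not analysed here. The other 38 lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Calls of members are counted as adjusted over all genes and as adjusted over the list alone. Added after the data were examined was an exact permutation test over all 126 splits of the libraries into 5 and 5, on the mean of a list minus the mean of all other genes, two-sided and adjusted over the 38 lists. Its smallest possible p is 0.00794, which came to 0.0126 after adjustment here because many lists shared it. Also added then was the count of lists called by camera in 99 other splits after each diet's mean was removed from every gene. Library totals and shares of reads were tested by exact permutation of log2(value + 1), two-sided. The resemblance of libraries was tested by an exact permutation, one-sided, on distances of 1 minus the Pearson correlation.

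Named genes followed a rule set before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes with a mean of at least 50 and no overlap between diets, up to 4 called members of each list by smallest adjusted p, up to 2 members where none was called, and w, InR, Thor, Ilp2, Ilp3, Ilp5, Gr43a, ple, Tbh and Tdc2 always. Genes outside it are said to be chosen after their values were seen.

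Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, TMM, upper-quartile and quantile scaling, the replicate number as a block, library weights, plain empirical Bayes, a test against 1.2-fold, both count models and leaving out each library in turn. Added after the data were examined were a scaling on the neuron markers, the leaving out of lists of other cell types, and upper-quartile scaling for the lists. The tests were checked on simulated counts for 9896 genes with the means, dispersions and depths of this comparison and 200 changed genes. limma recovered 68.0% of 50 genes changed 1.25-fold, 84.0% of 50 changed 1.5-fold and 100% of 50 each at 2-fold and 4-fold. Of its 185 calls 9 (4.86%) were false. The simulated genes were independent of each other, the true library factors were used, and changed genes had a mean of at least 50 and random directions. These rates therefore do not cover correlated genes, the choice of scaling, lower genes or a comparison with many changes that go mainly 1 way. Figures were drawn with matplotlib 3.10.9.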

Results

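Brain transcriptomes were compared between male flies on a diet of carbohydrate without protein (LPHC) and flies on a diet with 1 part protein to 2 parts carbohydrate (HPLC). Per the series design, LPHC lowered and HPLC raised the taste response to sucrose. Each diet had 5 libraries. Recovered reads per library were 30490786 ± 8025242 on LPHC and 27488346 ± 4545299 on HPLC (mean ± SD, n = 5 each), a difference within the spread (exact permutation p = 0.563). Of the 25 most abundant genes 10 were on the photoreceptor list. The labels give the tissue as brain and do not say whether retina was left on it, so values given here for brains may include eye tissue. ninaE, the main rhodopsin, took 5.78% ± 0.295 of reads on LPHC and 4.50% ± 0.361 on HPLC (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible). The 28 photoreceptor genes together took 12.5% to 13.7% of reads in the LPHC libraries and 9.27% to 11.5% in the HPLC libraries (exact permutation p = 0.00794).

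The comparison asks which brain transcripts differ between diets that set sucrose taste responses apart. On HPLC most genes called in the lists of amino acid breakdown, immune effectors, lipid breakdown, cytochrome P450, lipid synthesis and sugar use were higher, with list medians from 0.49 to 1.24 on the log2 scale. Fat body markers (17 of 18 higher) and haemocyte markers (8 of 15) rose in the same libraries. Glutathione transferases and genes of ribosomes, proteasome and endoplasmic reticulum chaperones were higher by less, with medians from 0.30 to 0.37. Called lower were 13 of 24 muscle, 11 of 16 activity-regulated and 8 of 18 heat shock genes, and 8, 2 and 6 under neuron-marker scaling. None of these lists was called by camera at an estimated correlation. Among insulin-like peptides, Ilp5 was 7.09-fold and Ilp2 1.45-fold higher on HPLC, and Ilp3 was 1.51-fold lower. limma called 4051 of 9896 genes, 2185 higher and 1866 lower on HPLC. Large changes went mainly up: of 663 called genes that differed at least 2-fold, 634 were higher and 29 lower, and of those that differed at least 4-fold, 213 were higher and 1 lower.

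The number of small changes in each direction depended on scaling. The higher share of calls was 53.9% as deposited and 58.7% with TMM (2274 higher, 1603 lower), 30.5% with upper-quartile scaling (1684 and 3832), 30.1% with quantile normalization (1682 and 3902) and 94.5% when libraries were scaled on neuron markers (3032 and 178). The median log2 fold change of all genes was −0.03 as deposited, −0.14 under both upper-quartile and quantile scaling and 0.15 under neuron-marker scaling. Changes below about that size, and some a little above it such as that of Tdc2 (−0.18 as deposited), have no fixed direction. For 2885 genes (29.2%) the 2 sets of 5 values did not overlap, against 0.794% by chance. Libraries resembled their own diet more than the other (mean distance 0.0320 between and 0.00641 within diets, exact permutation p = 0.00794, the smallest possible), and the first principal component, which held 73.4% of the variance, separated the diets.

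**Figure D1:**
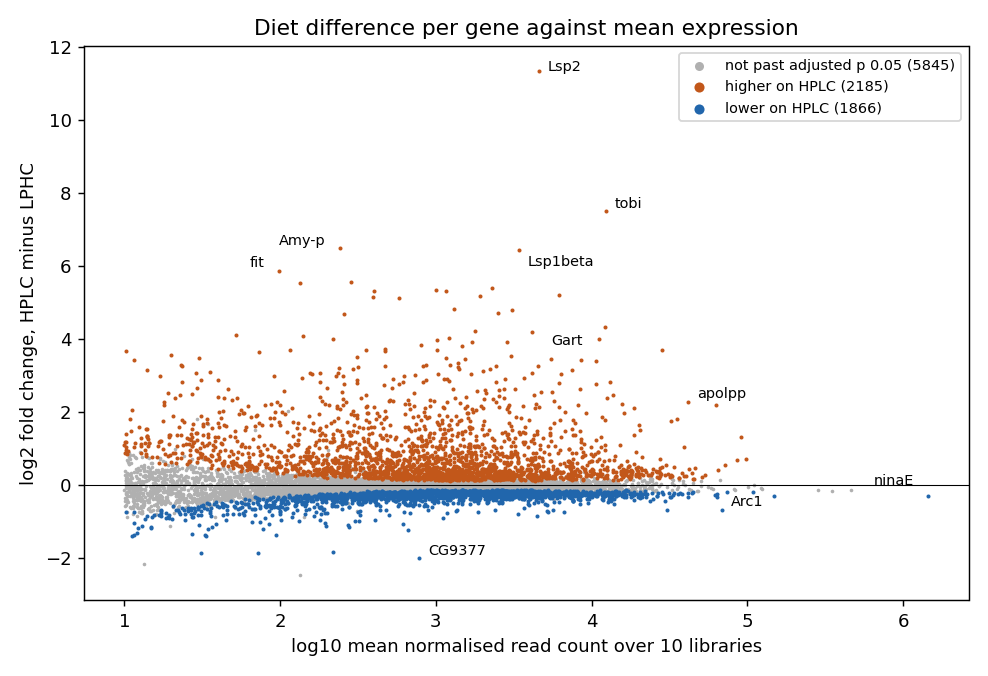
Log2 fold change of each of 9896 genes, HPLC minus LPHC, against the log10 mean normalised read count over 10 libraries; orange and blue points are genes called higher (2185) or lower (1866) by limma at adjusted p 0.05, grey points the rest. The largest changes lie above 0, up to 11.34 for Lsp2.

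The largest rise was that of Lsp2, a storage protein of the haemolymph, from a normalised read count of 3.25 ± 2.68 on LPHC (16 reads in all) to 9177 ± 1018 on HPLC (SD, n = 5 each), a log2 fold change of 11.34 ± 0.44 (SE, limma adjusted p = 2.96e-08). Another storage protein, Lsp1beta, rose from 76.9 ± 13.9 to 6713 ± 882, and tobi, an α-glucosidase, from 134 ± 12.5 to 24429 ± 3154 (log2 fold change 7.50 ± 0.08, limma adjusted p = 1.21e-18). The amylases Amy-p and Amy-d, near-identical copies whose reads may be shared, rose by 6.49 ± 0.28 and 5.32 ± 0.10 on the log2 scale. fit, a secreted peptide of the fat body tied to protein feeding, rose 74.5-fold. The other leading rises were the transporter Mdr50 (51.3-fold), CG3513 (55.6-fold), Gnmt (42.4-fold), the P450 Cyp309a1 (41.7-fold), CG1979 (40.9-fold) and the sorbitol dehydrogenase Sodh-1 (37.2-fold).

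Falls were smaller. Among the falls named by the rule, CG9377 had the largest, from 1231 ± 145 to 330 ± 140 (SD, n = 5 each; limma adjusted p = 5.04e-04), 3.74-fold as a ratio of means and the 1 fall of at least 4-fold on the fitted log2 scale. It was followed, as log2 fold changes, by slam (−1.86 ± 0.14), CG4269 (−1.83 ± 0.11), CG32368 (−1.23 ± 0.12), Nepl4, a neprilysin-like peptidase (−1.14 ± 0.14), CG14022 (−1.11 ± 0.11), CG17264 (−1.08 ± 0.11), phu (−1.07 ± 0.20) and Root, a protein of the ciliary rootlet (−1.02 ± 0.14). The inducible chaperone genes Hsp70Ab (−1.37 ± 0.20), Hsp70Bb (−1.19 ± 0.32) and Hsp70Bc (−1.05 ± 0.18) completed the rule's 12 falls. They are near-identical copies, so the reads of each are uncertain.

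Most amino acid catabolism genes rose. Of 33 tested genes of amino acid breakdown, 25 were called higher and none lower (26 and 0 adjusted over the list alone), with a median log2 fold change of 1.24 and members from −0.01 to 5.39. Gnmt, which methylates glycine, rose by 5.39 ± 0.09, Sardh, which oxidises sarcosine, by 4.81 ± 0.09, v, the first enzyme of tryptophan breakdown, by 2.54 ± 0.08, and Hn, phenylalanine hydroxylase, by 1.99 ± 0.06 (SE, limma adjusted p at most 5.36e-14). Camera called the list (adjusted p = 1.99e-36), but not with an estimated correlation (adjusted p = 0.0699). The amino acid shortage and ATF4 list split, with 7 of 18 higher and 4 lower (8 and 4 over the list alone). Of its 7 risers, 4 act in making serine or one-carbon units: Shmt (3.16 ± 0.08), Nmdmc (2.29 ± 0.07), CG6287 (1.47 ± 0.07) and aay (1.02 ± 0.06). Its median was 0.08 as deposited and turned to −0.01 under quantile and −0.04 under upper-quartile scaling, and camera called it up (adjusted p = 0.00388, 0.488 with an estimated correlation). Of 23 amino acid transporters 9 were higher and 6 lower (9 and 6 over the list alone), led by NAAT1 (0.73 ± 0.05), path (0.67 ± 0.06) and slif (0.79 ± 0.09), and the balance turned to 5 higher and 9 lower under quantile scaling (camera adjusted p = 0.885). Of 18 aminoacyl-tRNA synthetases 5 were higher and 1 lower (5 and 1 over the list alone; camera adjusted p = 0.944), with GluProRS at 0.26 ± 0.06, and under quantile scaling 1 was higher and 4 lower.

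Sugar and lipid genes rose together. Among 35 genes of sugar digestion, transport and glycolysis, 28 were higher and 1 lower (28 and 2 over the list alone), with a median of 0.49. Besides tobi and the amylases, Tps1, the trehalose synthase, rose from 3209 ± 346 to 22913 ± 2710 and fbp, of gluconeogenesis, from 661 ± 32.8 to 3388 ± 340 (SD, n = 5 each). Of 26 genes of lipid synthesis and sugar sensing, 16 were higher and 2 lower (17 and 2 over the list alone; median 0.60), among them the fatty acid synthase FASN1 (1.81 ± 0.09), Desat1 (1.76 ± 0.08), Men (1.98 ± 0.07) and AcCoAS (1.65 ± 0.07). Of 18 genes of lipid breakdown and fasting, 15 were higher and none lower (16 and 0 over the list alone; median 0.86), led by the lipid droplet protein Lsd-1 (2.60 ± 0.08), yip2 (1.51 ± 0.05), CPT2 (1.08 ± 0.06) and Acox57D-p (1.23 ± 0.07). Camera called these 3 lists (adjusted p = 2.37e-22, 2.49e-07 and 1.65e-10), and with an estimated correlation the adjusted p were 0.0801, 0.202 and 0.0801.

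Fat body markers, of the tissue that stores fat and makes haemolymph proteins and can adhere to a dissected brain, moved with the diet. Of 18 tested, 17 were higher and 1 lower (17 and 1 over the list alone), with a median log2 fold change of 1.41 and a share of reads of 0.153% ± 0.0135 on LPHC and 0.577% ± 0.0450 on HPLC (SD, n = 5 each, exact permutation p = 0.00794). The rises differed widely between members: 11.34 for Lsp2, 4.81 ± 0.08 for CG34166, 2.29 ± 0.09 for apolpp, the lipophorin precursor, and 1.47 ± 0.06 for Mtp. The metabolic, detoxification and immune genes of the other lists rose beside these markers in the same libraries. Some markers are members of those lists too: Gnmt and ppl of amino acid breakdown, FASN1 of lipid synthesis, and Lip4 and AkhR of lipid breakdown. Haemocyte markers were also higher, 8 of 15 with none lower (8 and 0 over the list alone; median 0.79; 14 and 0 under neuron-marker scaling), led by Glt (3.47 ± 0.11), NimB5 (1.45 ± 0.14) and eater (1.19 ± 0.21). Of 7 gut and salivary enzymes, 4 were higher and 1 lower (4 and 1 over the list alone), with Amy-p, Amy-d, Mal-B1 (0.96 ± 0.10) and Mal-A1 (0.79 ± 0.11) the risers; all 4 also stand in the sugar list. Camera called the 3 lists (adjusted p = 3.04e-28, 0.0436 and 2.29e-06; 0.0801, 0.568 and 0.206 with an estimated correlation), and the haemocyte call was lost without LPHC replicate 3, HPLC replicate 2 or HPLC replicate 3 (adjusted p up to 0.0903) and with a mean of at least 50 (0.0593). Without the 203 tested genes of these and the other cell type and immune lists, 3931 genes were called, 2100 higher and 1831 lower. Leaving out so few genes cannot show whether RNA of other tissues matters, since unlisted genes of those tissues stay in.

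Immune effectors rose broadly. Of 39 tested genes of antimicrobial peptides and immune effectors, 35 were higher and none lower (37 and 0 over the list alone), with a median of 1.10. The recognition proteins PGRP-SD (3.28 ± 0.10), PGRP-SB1 (2.46 ± 0.13) and GNBP3 (1.66 ± 0.07) and the peptide AttB (3.06 ± 0.17), whose reads may be shared with its copy AttA, led by adjusted p. Haemocyte and fat body markers were higher in the same libraries. Of 9 Turandot and JAK-STAT genes 5 were higher and 1 lower (5 and 1 over the list alone), with TotA at 1.59 ± 0.08, TotX at 1.10 ± 0.17, TotM at 1.31 ± 0.25 and Stat92E at 0.64 ± 0.07. Camera called the immune list (adjusted p = 5.60e-13, 0.202 with an estimated correlation) and not the Turandot list (0.194).

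Detoxification families and odorant binding proteins also rose. Of 73 cytochrome P450 genes 47 were higher and 7 lower (47 and 7 over the list alone; median 0.68), led by Cyp309a1, Cyp6a8 (3.55 ± 0.08), Cyp6w1 (2.57 ± 0.07) and Cyp4e2 (2.15 ± 0.07). Of 29 glutathione transferases 19 were higher and 1 lower (19 and 1 over the list alone; median 0.34), with GstE9 at 2.60 ± 0.11, GstE7 at 1.90 ± 0.09 and GstS1 at 1.44 ± 0.06. Of 28 odorant binding proteins 17 were higher and 1 lower (17 and 1 over the list alone; median 0.54), with Obp99b at 4.21 ± 0.17, Obp56a at 3.08 ± 0.16 and Obp99c at 3.04 ± 0.09; Obp99b is also on the fat body list. Camera called these families (adjusted p = 1.18e-17, 1.87e-04 and 1.54e-04), with adjusted p of 0.0801, 0.419 and 0.426 at an estimated correlation.

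Protein synthesis, turnover and folding changed by smaller amounts. Of 84 cytosolic ribosomal protein genes 68 were higher and none lower (75 and 0 over the list alone, median 0.31), led by RpLP2 (0.72 ± 0.07), RpS5a (0.58 ± 0.07) and RpL10 (0.52 ± 0.07). Under upper-quartile scaling 49 were higher and 1 lower (median 0.20), and under neuron-marker scaling 78 and 0 (median 0.49). Of 32 proteasome genes 29 were higher and none lower (31 and 0 over the list alone; median 0.30), with Rpn6 at 0.38 ± 0.05 and Prosalpha6 at 0.43 ± 0.06; 18 were higher under upper-quartile and 15 under quantile scaling. Of 15 endoplasmic reticulum chaperone genes 11 were higher and none lower (12 and 0 over the list alone; median 0.37), led by Gp93 (0.98 ± 0.06), Pdi (0.85 ± 0.06) and Hsc70-3 (0.66 ± 0.07). Camera called these lists (adjusted p = 0.00191, 0.0153 and 0.00390; 0.527, 0.516 and 0.307 with an estimated correlation), and the proteasome call was lost under neuron-marker scaling (0.103). In contrast, 8 of 18 heat shock and folding genes were lower and 1 higher (8 and 1 over the list alone), with Hsp83 at −0.67 ± 0.07, DnaJ-1 at −0.51 ± 0.06 and Hsp70Aa at −1.85 ± 0.29; the median of −0.14 turned to 0.04 under neuron-marker scaling, with 6 lower and 5 higher. Camera did not call the list (adjusted p = 0.0623), except, as lower than other genes, without LPHC replicate 1 (0.0398) and under neuron-marker scaling (0.0311).

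Mitochondrial lists differed little. None of 72 mitochondrial ribosomal protein genes was called by limma (0 over the list alone; median 0.00 in size), with mRpL46 at 0.18 ± 0.07 (limma adjusted p = 0.0633; 0.0110 without LPHC replicate 1) and mRpS30 at 0.11 ± 0.05 (0.104); under quantile scaling 19 were lower. Of 66 oxidative phosphorylation genes 9 were higher and 1 lower, and none over the list alone; ATPsyngamma was at 0.27 ± 0.07 and ATPsynC at 0.26 ± 0.07, and under quantile scaling none was higher and 4 lower. The list's median was 0.08 and its mean 0.06, while camera pointed down (adjusted p = 0.927; mitochondrial ribosomal proteins 0.409). Autophagy genes moved both ways, 5 of 19 higher and 5 lower (5 and 5 over the list alone), with Atg13 at 0.88 ± 0.06, Atg4a at 0.75 ± 0.06 and Atg101 at −0.41 ± 0.05; the median (−0.06) and camera (adjusted p = 0.934) pointed down and the mean (0.05) up, and the counts turned to 3 higher and 9 lower under quantile scaling.

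Insulin signalling genes split by gene. Of 24 genes of insulin and TOR signalling 7 were higher and 5 lower (7 and 5 over the list alone), and 7 and 11 under quantile and 11 and 2 under neuron-marker scaling. Ilp5, an insulin-like peptide of the brain, rose from 44.6 ± 10.3 to 316 ± 19.9, Ilp2 from 3982 ± 449 to 5764 ± 513 and Ilp6 from 379 ± 35.0 to 1085 ± 79.9, and ImpL2, an insulin-binding protein, rose by 0.93 ± 0.10. Ilp3 fell from 219 ± 38.0 to 145 ± 27.1 (log2 fold change −0.59 ± 0.14, limma adjusted p = 0.00311; 0.0811 under neuron-marker scaling). The insulin receptor InR fell from 2945 ± 377 to 1855 ± 221 (−0.67 ± 0.10, 5.15e-05) and Thor, the translation repressor 4E-BP, from 5755 ± 512 to 3177 ± 213 (SD, n = 5 each; limma adjusted p = 1.99e-08). The list's median was −0.06, its mean 0.14 and camera pointed up (adjusted p = 0.927).

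**Figure D2:**
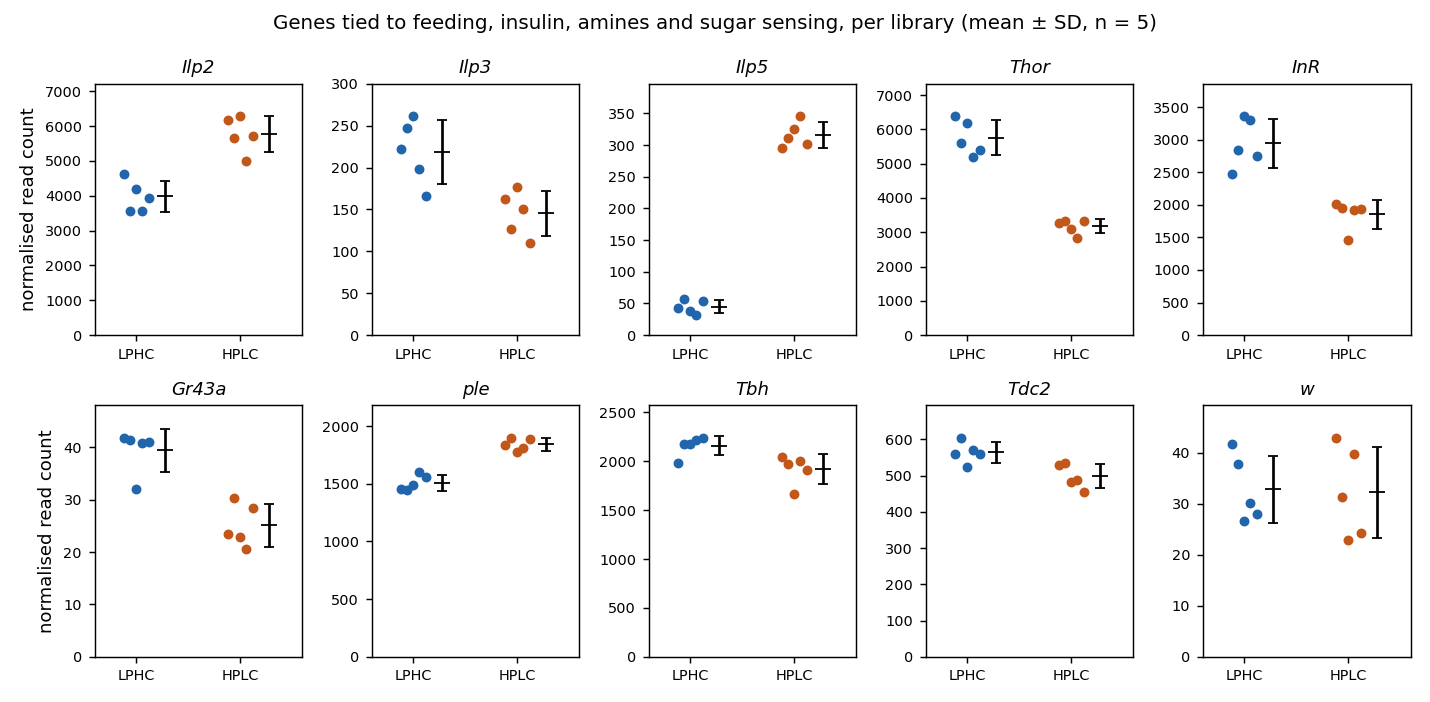
Normalised read count of the 10 genes reported whatever their result, per library, for LPHC (blue) and HPLC (orange), with the mean and SD of 5 libraries beside the points and each axis starting at 0. Ilp5 is 7.09-fold higher on HPLC without overlap, and w is at 32.8 and 32.2.

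Camera called none of the taste and amine lists as deposited. In the exact permutation of list means against all other genes, the taste and feeding list was lower by a difference of −0.42 and the amine list by −0.13 (adjusted p = 0.0126 for both, from the smallest possible p). The desensitisation list did not pass (0.08, adjusted p = 0.0905). That test moves diet labels only and does not set a list apart from other sets of genes. The mean of all genes was 0.12, and the amine list's own mean was −0.01 (adjusted p = 0.742) against −0.31 for the taste list (0.0232). Of 19 taste and feeding chemoreceptor genes 4 were lower and none higher (4 and 0 over the list alone; median −0.24), against 11 lower under upper-quartile, 12 under quantile and none under neuron-marker scaling. Gr43a, a receptor for fructose in the brain, fell from 39.4 ± 4.10 to 25.2 ± 4.10 (log2 fold change −0.63 ± 0.17, limma adjusted p = 0.00729, and 0.0766 under neuron-marker scaling), beside the channels ppk25 (−0.58 ± 0.12), ppk29 (−0.53 ± 0.12) and ppk23 (−0.57 ± 0.19). No other member of the list was called as deposited, and these 4 were low, with diet means from 25.2 to 150. The list's camera adjusted p was 0.0947, and 0.0170, as lower than other genes, under neuron-marker scaling. Of 14 factors linked to diet-driven taste desensitisation, 2 were higher and 3 lower (2 and 3 over the list alone), and 1 and 8 under quantile scaling. Gart, an enzyme of purine synthesis on that list, rose from 1289 ± 65.8 to 20883 ± 3876, while bigmax (−0.32 ± 0.06) and Pc (−0.23 ± 0.07) fell, calls lost under neuron-marker scaling (adjusted p = 0.372 and 0.743). The median was −0.08, while the mean (0.19) and camera (adjusted p = 0.885) pointed up. Of 30 genes of dopamine, serotonin and octopamine 5 were higher and 12 lower (5 and 15 over the list alone; camera adjusted p = 0.467), against 3 and 18 under both upper-quartile and quantile scaling and 6 and 0 under neuron-marker scaling. The largest rise was that of Hn (1.99 ± 0.06), which is also on the amino acid breakdown list. ple, the tyrosine hydroxylase of dopamine synthesis, rose from 1510 ± 68.9 to 1840 ± 52.2 (0.29 ± 0.05, 1.85e-04) and Pcd by 0.34 ± 0.07. Tbh and Tdc2, of octopamine synthesis, were at −0.17 ± 0.06 and −0.18 ± 0.06 (limma adjusted p = 0.0339 and 0.0320). Tbh lost its call without any 1 of 6 libraries (LPHC replicates 2, 3, 4 and 5 and HPLC replicates 3 and 5; adjusted p up to 0.0788) and Tdc2 without any 1 of 5 (LPHC replicates 2, 4 and 5 and HPLC replicates 4 and 5; up to 0.0924) and under TMM (0.0543), and both had values of about 0 under neuron-marker scaling. w, which the genotype mutates, was at 32.8 ± 6.60 and 32.2 ± 8.94 (SD, n = 5 each; limma adjusted p = 0.879).

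The neuropeptide and hormone list held some large rises among many small falls. Of 36 neuropeptide and hormone genes 6 were higher and 13 lower (6 and 15 over the list alone), against 6 and 25 under upper-quartile, 6 and 24 under quantile and 6 and 3 under neuron-marker scaling. Nplp2 rose from 2692 ± 368 to 18536 ± 2531 and CCHa2, a nutrient-responsive peptide, from 526 ± 82.3 to 3161 ± 479, while Hug fell by 0.54 ± 0.08 on the log2 scale. The median was −0.20 and camera pointed down (adjusted p = 0.589), while the mean was 0.07. Of 38 peptide receptors 3 were higher, PK1-R (1.22 ± 0.10), AkhR (1.38 ± 0.12) and CrzR (0.32 ± 0.06), and 17 lower (6 and 20 over the list alone); 3 were higher and 26 lower under quantile scaling, and 9 higher and none lower under neuron-marker scaling (camera adjusted p = 0.0873). AkhR is also on the fat body list. Fat body markers rose in the same libraries, and which cells gave the reads of Nplp2 and CCHa2 is not known here.

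The medians of the fast transmitter, synaptic, neuron and photoreceptor lists lay slightly below 0 as deposited and under TMM, upper-quartile and quantile scaling. Neuron-marker scaling sets neuron genes to about 0 by construction. Of 30 genes of fast transmitters and their receptors 16 were lower and 1 higher (17 and 2 over the list alone; median −0.18), with nAChRbeta2 at −0.32 ± 0.05, nAChRalpha2 at −0.30 ± 0.05 and Lcch3 at −0.33 ± 0.06. As many as 26 were lower and none higher under upper-quartile and quantile scaling, and none lower and 3 higher under neuron-marker scaling. Of 25 synaptic vesicle and active zone genes 7 were lower and none higher (7 and 0 over the list alone; median −0.15), with Rim at −0.28 ± 0.08. There were 19 lower under both upper-quartile and quantile scaling, and none lower and 1 higher under neuron-marker scaling. Of 12 neuron markers 5 were lower and none higher (7 and 0 over the list alone; median −0.20), with para, the sodium channel, at −0.32 ± 0.08. The count lower was 9 under both upper-quartile and quantile scaling, and none lower and 2 higher when scaled on themselves. Of 28 photoreceptor genes 12 were lower and 1, ninaB (0.49 ± 0.06), higher (12 and 1 over the list alone; median −0.18), with ninaE at −0.30 ± 0.07. Of them 19 were lower under upper-quartile and 16 under quantile scaling, and none was lower and 1 higher under neuron-marker scaling. Of these 4 lists camera called the fast transmitter list (adjusted p = 0.0153, 0.523 with an estimated correlation), and not the synaptic (0.0633; 0.0237 without LPHC replicate 1), neuron (0.191) or photoreceptor list (0.0536, and called without any 1 of LPHC replicate 1 and HPLC replicates 3, 4 and 5, adjusted p down to 0.0360). Of 16 activity-regulated genes 11 were lower and none higher (11 and 1 over the list alone; median −0.28), led by Arc1, from 84585 ± 7369 to 53164 ± 5264, and CG14186 (−0.40 ± 0.07); 2 were lower and 1 higher under neuron-marker scaling (camera adjusted p = 0.0177, 0.350 with an estimated correlation).

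Markers of other cell types moved in different directions. Of 24 muscle genes 13 were lower and none higher (13 and 0 over the list alone; median −0.28), with Act87E at −0.69 ± 0.05, TpnC41C at −0.73 ± 0.09 and Zasp66 at −0.52 ± 0.06; 8 were lower and 2 higher under neuron-marker scaling (camera adjusted p = 0.00126, 0.202 with an estimated correlation). Of 15 glia markers 6 were higher and none lower (6 and 0 over the list alone; median 0.24), against 2 higher under upper-quartile, 4 under quantile and 11 under neuron-marker scaling, among them Indy (0.78 ± 0.06) and the trehalose transporter Tret1-1 (0.55 ± 0.07), which is also on the sugar list (camera adjusted p = 0.457). Of 42 cuticle and trachea genes 13 were higher and 8 lower (13 and 8 over the list alone; camera adjusted p = 0.686), with Cpr11B at 1.72 ± 0.13 and Cpr60D at 1.74 ± 0.13; the median of 0.10 turned to −0.04 under quantile scaling, and 15 were higher and 1 lower under neuron-marker scaling. The list's share of reads went the other way from its mean, from 0.105% ± 0.00736 to 0.0927% ± 0.00598 (SD, n = 5 each, exact permutation p = 0.0159). Of 15 testis and accessory gland genes 3 were higher and 4 lower (3 and 4 over the list alone), with Est-6 at 2.35 ± 0.11 and Mst85C at −0.32 ± 0.07, against 3 and 0 under neuron-marker scaling; the median (−0.16) and camera (adjusted p = 0.927) pointed down and the mean (0.13) up. Of 17 circadian clock genes 4 were higher and 2 lower (3 and 2 over the list alone), with cwo at 0.55 ± 0.08, cry at 0.39 ± 0.07 and tim at 0.33 ± 0.07; the median (−0.04) and camera (adjusted p = 0.927) pointed down and the mean (0.05) up, and the counts were 3 higher and 7 lower under upper-quartile, 3 and 4 under quantile and 8 and 0 under neuron-marker scaling.

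**Figure D3:**
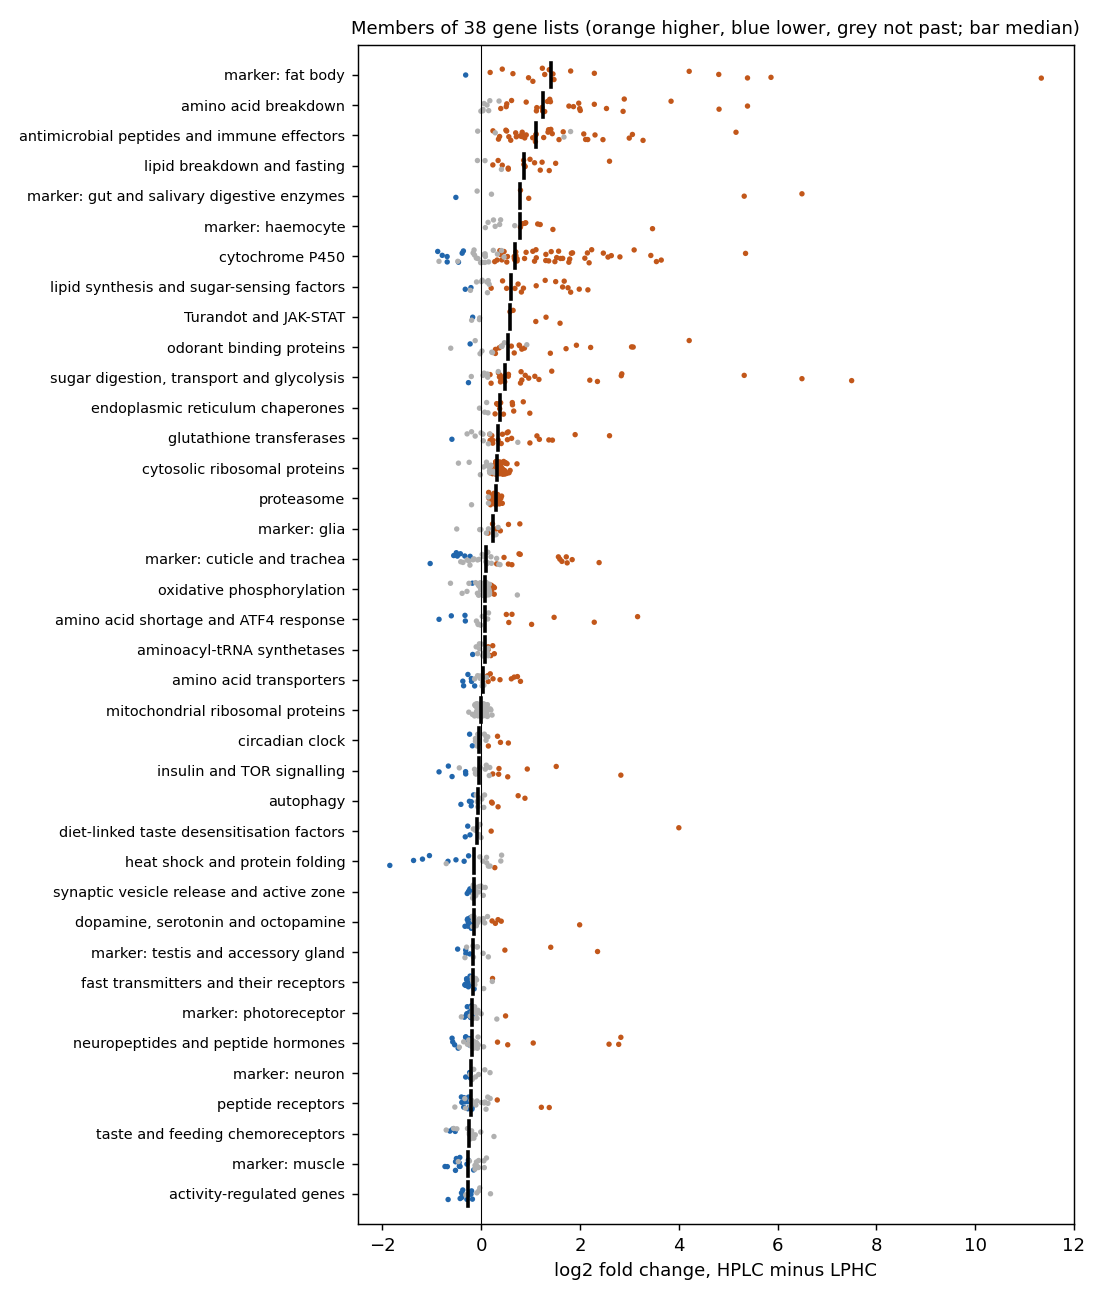
Log2 fold change, HPLC minus LPHC, of each member of the 38 tested gene lists, ordered by the list median (black bar); orange and blue points passed limma adjusted p 0.05 and grey points did not. Medians run from −0.28 for activity-regulated genes to 1.41 for fat body markers; some of those within about 0.2 of 0 change sign with the scaling used.

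By list test, camera called 18 of 38 lists at the preset correlation, 15 up and 3 down, and none with an estimated correlation (smallest adjusted p 0.0699; 9 at an unadjusted p under 0.05; fry called 30). The preset count is weak evidence on its own: with each diet's mean removed from every gene, 18 of 99 other splits of the libraries gave 18 or more lists. In the exact permutation of list means against all other genes, 28 lists passed at an adjusted p of 0.05, 17 higher and 11 lower. These are relative to all other genes, and the mean of all genes was 0.12 where their median was −0.03. The list's own mean passed in the same direction for all 17 higher and for 7 of the 11 lower. The other 4 were the amine, synaptic and neuron lists, whose own mean did not pass, and autophagy, whose own mean rose (0.05, adjusted p = 0.0323). The permutation moves diet labels and draws no random gene lists, so passing does not set a list apart from other sets of genes. A small gap passes where the libraries of a diet agree closely, as for autophagy (−0.07 against other genes).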

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

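The tests in this part were set before the results were seen. In each diet, the highest and the lowest of the 5 libraries was compared with its nearest neighbour for every named gene, for recovered reads and for the ninaE share of reads. Of 342 such groups 18 had a library far from the other 4 (5.26%), where chance gives about 5%. HPLC replicate 3 held 6 of the 18 and LPHC replicate 1 held 4. No explanation, technical or biological, was tested for these.

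In HPLC replicate 3, the normalised read count of InR was 1464 (other HPLC libraries 1914 to 2012), of tim 23810 (27710 to 28760), of EndoA 12290 (13280 to 13600), of ATPsynO 8816 (7107 to 7530), of Obp57b 1773 (1324 to 1449) and of TpnC41C 602.1 (419.9 to 465.5). In HPLC replicate 2, that of Hn was 9493 (10770 to 11210), and in HPLC replicate 1, that of Ptx1 was 451.5 (316.9 to 351.3).

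In LPHC replicate 1, the normalised read count of Nepl4 was 251.7 (other LPHC libraries 397.8 to 450.4), of Root 181.5 (269.3 to 294.5), of eater 95.97 (198.2 to 231.6) and of Tbh 1988 (2176 to 2237). In LPHC replicate 5, that of Hsp70Ab was 231.4 (92.49 to 131.9), of Hsp70Bc 186.6 (86.87 to 107.8) and of Obp99b 273.4 (145.9 to 178.6). That of CG17264 was 442.8 in LPHC replicate 2 (340.6 to 364.8), of Gr43a 32.1 in LPHC replicate 3 (40.75 to 41.72) and of jet 540.5 in LPHC replicate 4 (643.5 to 663.3). Leaving out the library given here for each of the 18 genes changed the call of 1 of them, ATPsynO, which was no longer called (limma adjusted p = 0.0528 without HPLC replicate 3).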

How the results depend on the processing

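Neuron-marker scaling, leaving out the lists of other cell types and upper-quartile scaling of the lists were tests chosen after the data were seen. The count of called genes stayed between 3210 and 5584 in the alternatives, except against a 1.2-fold threshold (1275 genes, 1132 higher and 143 lower, fewer because that test asks for more). The lower count moved to 3832 with upper-quartile scaling, 3902 with quantile normalization and 178 with neuron-marker scaling, whose factors shift all genes together. Calls of at least 2-fold numbered 536 to 795. edgeR called 4032 genes, 3964 of them called by limma in the same direction, and DESeq2 4150, of which 3987 were shared so. Without 1 library, 3450 to 4133 genes were called, 17 to 21 lists by camera, and the separation of diets was 0.0251 to 0.0263.

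Camera called 0 lists with an estimated correlation (9 at an unadjusted p under 0.05), which allows for more correlation within a list, and fry, which asks another question, called 30. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated across genes at −0.0247 to 0.00500, and 0 of 10 libraries correlated best with its own number. With the replicate number as a block 3854 genes (2152 higher, 1702 lower) and 18 lists were called, and onecut and Tbh lost their calls (adjusted p = 0.0507 and 0.0511).

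Of single genes, mRpS30 turned to −0.0222 under quantile normalization, and under neuron-marker scaling TrpRS turned to 0.00703, Tbh to 0.0102, Tdc2 to 0.00171 and w to 0.127 (log2 fold changes, none called). Over the libraries left out in turn, w ran from −0.158 to 0.0595, above 0 without LPHC replicate 1 or 2 or HPLC replicate 3 or 5, and was never called. ATPsynO, onecut, COX7A, Frq1, Syt1, Ptx1, wrapper, Rbp9, ppk23, Tbh and Tdc2 each lost their call without any 1 of up to 6 libraries (adjusted p up to 0.0924).

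List directions turned as follows, with the adjusted p: under upper-quartile scaling the aminoacyl-tRNA synthetases (0.839) and testis (0.951); under quantile normalization the synthetases (0.824), oxidative phosphorylation (0.957) and testis (0.992); with the block testis (0.936); with an estimated correlation oxidative phosphorylation (0.876), taste desensitisation (0.581) and clock (0.895). With fry they turned for mitochondrial ribosomal proteins (0.968), oxidative phosphorylation (0.374), autophagy (0.0214), clock (0.223) and testis (0.220), and under neuron-marker scaling for autophagy (0.952) and clock (0.784). Over the libraries left out in turn, the adjusted p was 0.891 to 0.993 for the synthetases (turned without LPHC replicate 3 or HPLC replicate 4), 0.820 to 0.997 for insulin and TOR (LPHC replicate 1), 0.544 to 0.993 for oxidative phosphorylation (LPHC or HPLC replicate 1), 0.884 to 0.993 for autophagy (LPHC replicate 1) and 0.869 to 0.978 for the clock (HPLC replicate 3). Beyond the shift that scaling factors make, the cause was not tested. Depth limits the folds of genes with few reads on LPHC, such as fit (13 reads over 5 libraries) and Lsp2 (16).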

Other observations

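All tests of explanations in this part, the counts of splits included, were written down after the results were seen, and the genes of the first 2 paragraphs were chosen after their values were seen. Genes of purine synthesis and one-carbon metabolism rose strongly on HPLC. Of 10 purine synthesis genes 7 were higher and 1 lower, with a median log2 fold change of 2.20. Prat2, the first step of the pathway, rose from 429 ± 29.8 to 7853 ± 711 and Paics from 1528 ± 98.6 to 10744 ± 1178 (normalised read counts, SD, n = 5 each), while Prat, the second gene for the first step, fell by 0.24 on the log2 scale (limma adjusted p = 0.0439). Of 9 folate and one-carbon genes 8 were higher and none lower, led by CG3999 (log2 fold change 5.13 ± 0.14) and pug, which rose from 1147 ± 31.8 to 23251 ± 3048. All 5 genes of sugar alcohol and galactose use that were looked at were higher, among them Galk (2.93 ± 0.06) and Galt (1.83 ± 0.07).

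Some of the most abundant transcripts also rose. Tsf1, an iron-binding transferrin, went from 22785 ± 3693 to 103250 ± 7521 and eEF1alpha1, a translation elongation factor, from 51813 ± 4193 to 128675 ± 13498 (SD, n = 5 each; limma adjusted p = 5.94e-12 and 6.00e-10).

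Of 100 splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many called genes (4051, highest other 1). The same held for genes higher (2185, highest other 1), lower (1866, highest other 1) and at 2-fold (663, highest other 0). These counts do not decide on chance, because other splits put the diet difference into the spread within their groups, which keeps their counts low. A chance difference between cultures is not excluded either, since the labels do not say whether libraries came from separate cultures. Chance cannot be excluded for the count of 18 lists by camera at the preset correlation, since 47 of 100 splits gave as many and the highest other gave 26. Splits with 4 libraries of 1 diet on a side keep much of the diet difference, and 20 of 21 such splits gave as many. With each diet's mean removed from every gene, 18 of 99 splits still gave 18 or more lists, up to 27.

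Fat body genes were higher on HPLC. The 5 scalings put the median of all genes between −0.14 and 0.15 and that of this list at 1.30 or above. This argues against scaling by such amounts only, since shifts that small could not have removed the rise. More fat body tissue on the HPLC brains cannot be told apart from a change of expression: 17 of 18 members rose, but by unequal amounts, with an SD of 2.86 of their log2 fold changes against a median SE of 0.0991. The most abundant members, apolpp and FASN1, went from 14098 to 68600 and from 15699 to 55140 normalised reads (means, n = 5 each), and how much of either comes from brain cells is not known here. An effect of the diet on these genes stays open as a hypothesis.

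Immune effectors were higher on HPLC. The 5 scalings put the median of this list at 0.96 or above and that of all genes between −0.14 and 0.15. Again this argues only against scaling by such amounts, which could not have removed the rise. More haemocytes in the HPLC samples cannot be told apart from induction of these genes: the haemocyte list also rose, by a median of 0.79, below the immune median of 1.10. On the haemocyte list 8 of 15 members were called higher and none lower, among them Glt (911 to 10028.5 normalised reads). Ppn (8146 to 9754) and crq (5305 to 5831), abundant members chosen after their values were seen, were not called (limma adjusted p = 0.390 and 0.148). A high level of these from other cells would hide a small added share. More fat body tissue, whose markers rose in the same libraries, different microbes in the foods and an effect of the diet itself stay open, untested.

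Of 64 neuron, synapse and transmitter genes, 27 were called lower and 1 higher on HPLC as deposited. Their median was −0.16 as deposited and ran from −0.15 under TMM to −0.27 under upper-quartile scaling. Neuron-marker scaling, built on part of these genes, put it at 0.02. A lower share of neuron RNA with every other cell type raised alike is argued against by the muscle list, whose median was −0.28 while that of fat body markers was 1.41. Library scaling as the whole cause is argued against by the gap between the medians of these and of all other genes, which 1 factor per library cannot make. The gap was −0.16 as deposited (exact permutation p = 0.0238) and −0.15 under quantile normalization (p = 0.0159). TMM and upper-quartile scaling use 1 factor per library, so they repeat the deposited gap and add no test. The 64 genes were pooled after the results were seen, so these p-values come from the data that chose the pattern. The gaps are relative to other genes, so they do not show whether the amount per neuron fell. RNA added from a single other tissue and an effect of the diet on neurons stay open, untested.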
